A study of Mus musculus with 8 samples.

How the data were processed

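RNA from thioglycollate-elicited peritoneal macrophages was hybridised to 8 Affymetrix arrays, 2 in each of 4 groups defined by genotype (wild type or IFN-beta null) and labelled infection (mock or *Salmonella* Typhimurium). The deposited table holds log2 values for 72688 probe sets. Per the submitters' processing notes the values were made with Affymetrix Expression Console, and its version, summarization and normalization were not given in the sources used here. The values ranged from 0.934 to 14.2, and array medians differed by under 0.2, so no further normalization was applied in the reported fits. No pair of arrays shared all values.

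Probe sets were named through the platform annotation, which lists 32750 of them. Of these, 30604 had 1 gene symbol and 2146 had several. A further 39752 had no symbol here, and 186 were controls or spike-ins. Symbols of 22818 probe sets were looked up through a gene ID in a RefSeq gene table (GRCm38.p6, used for names only), which changed 827 symbols. Probe sets with no or several symbols were left out. Of the genes, 355 had more than 1 probe set, and each was represented by the one with the highest mean over all 8 arrays, leaving 30142 genes. Probe sets disagreed for some genes: between replicate numbers in wild type, those of Fas gave -0.60 and 2.45, those of Irf1 1.07 and 3.12, and those of Scd1 -0.47 and 0.14. Probe sets of near-identical families, such as Ifit3 and Ifit3b, Ifi208 and Ifi213 or the Slfn genes, can share signal, so the values of single members are uncertain.

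Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes), with 1 mean per labelled group and Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. All tests were 2-sided, and adjusted p values are limma's unless a list test is named. Every array stayed in its labelled group. The 5 comparisons by label were infection in each genotype, genotype in mock cells, genotype in infected cells and their interaction. Residual degrees of freedom were 4 in the fit by group and 3 in the fits with the replicate block or by number. The groups, tests, alternatives, gene lists and naming rule were fixed before the data were examined. The 5 comparisons by replicate number, with arrays grouped by genotype and number and the labelled infection as an additive term, were added after the values had been seen, as was a list of 1869 small nuclear and nucleolar RNAs taken by biotype.

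The labels give each group replicates 1 and 2. Over the group means, the deviations of same-numbered arrays correlated across genes at 0.617 to 0.863 in the 6 pairs, so the numbers were taken to pair the arrays, and fits with the number as a block are given where they change a call. The labels call the arrays biological replicates and do not say what a number shares.

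Genes were named by rule. Ifnb1 is given on every array. Per comparison the 8 genes with the highest and the 8 with the lowest log2 difference (5 each for genotype in mock cells and for interactions) were taken among those past the threshold whose arrays did not overlap. Where none passed in a direction, the 3 with the smallest p are given as not passing. Provisional symbols were skipped. The same rule was kept for the added comparisons and for the blocked fit in wild type. Up to 4 members are named per gene list, those past the threshold first.

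The 28 gene lists covered interferon responses, inflammation, antigen presentation, metabolism, stress and markers of other cells of the peritoneum. They were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, both adjusted over the 28 lists, and with fry, unadjusted. Fry results are given only for infection by label. No call of these 28 lists in the 5 comparisons by label held with an estimated correlation, with or without the block. That correlation is estimated from the residuals, which without the block include the difference between numbers. The block is 1 number term shared by both genotypes. With it the residuals still hold the part of the difference between numbers that differed between genotypes, as for the interferon-stimulated genes. For the cytokine list the estimated correlation was 0.826 without the block and 0.0173 with it, and for the interferon-stimulated list 0.939 and 0.941.

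The fits were tested on simulated data with the spread of the real genes, in 10 runs over 30142 genes with 50 genes changed at each of 4 sizes. For infection in wild type, 1.20% of the genes changed by a log2 value of 0.5 were recovered, 61.2% at 1, 92.0% at 2 and 96.6% at 3, with 79 false calls over the runs. For the difference between numbers in wild type, 51.8%, 99.8%, 100% and 100% were recovered, with 166 false calls. A list shifted by 0.5 was found in 9 of 10 runs for infection in wild type and in 10 of 10 for the numbers, by camera at the preset correlation. The simulated genes varied independently of each other and held no shared difference between numbers. These rates therefore do not show how the fits and list tests behave with correlated genes. The changed genes were drawn at random from all genes. Genes with a large difference between numbers, as in the cytokine, chemokine and interferon-stimulated lists, had a larger spread in the fit by group. The rates for infection in wild type therefore do not hold for such genes.

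Alternatives were the replicate block, quantile normalization, leaving out the 40% of genes with the lowest mean, the mean of all probe sets of a gene, every probe set on its own, trend and robust moderation, a minimum log2 difference of 1, a fit to the arrays of the compared groups alone, and leaving out each of the 8 arrays in turn. For the comparisons by number, a fit without the label term was added. Bootstrap intervals over list members used 10000 resamples. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.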

Results

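RNA abundance was measured on 8 Affymetrix arrays in peritoneal macrophages elicited with thioglycollate, an irritant that recruits monocyte-derived macrophages into the peritoneal cavity. The cells came from wild-type mice and from mice lacking IFN-beta, the type I interferon that macrophages secrete on sensing bacteria. They were labelled either mock-infected or infected with *Salmonella* Typhimurium at a multiplicity of 4 for 30 min, with RNA taken at 6 h. The 4 groups each held 2 arrays labelled as biological replicates and numbered 1 and 2. Array medians over all probe sets lay between 5.31 and 5.50 on the log2 scale, and the medians of the background probe sets lay between 3.85 and 4.06. The small number of arrays limits the precision of every comparison. In the group where they were lower, Il6, Cd69, Cpa3, Ccl12, Ifit1bl1, Serpinb2, Mir450-2 and Vmn2r96 lay at about the background medians or below them, and Olfr728 lay below them on every array. The size of their differences is therefore uncertain, and no fold is given for them.

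Ifnb1, the gene missing from the null mice, was low on every array. Its log2 values were 4.52 and 4.78 on the wild-type mock arrays, 4.27 and 4.59 on the wild-type arrays labelled infected, 4.81 and 4.96 on the null mock arrays, and 4.69 and 4.73 on the null arrays labelled infected. The mean stood at the 26.4th percentile of the genes tested. The null minus wild-type difference was 0.24 ± 0.15 (SE, adjusted p = 0.632) in mock cells and 0.28 ± 0.15 (adjusted p = 1.0) in cells labelled infected. The probe set's place relative to the deleted part of the gene was not given in the sources used here, so Ifnb1 does not check the genotype labels.

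Arrays with the same labels held different inflammatory programmes. Il6, a cytokine of acute inflammation, was at 3.60 and 11.24 on the wild-type mock arrays numbered 1 and 2, and at 3.88 and 11.37 on the wild-type arrays labelled infected. In the null macrophages it was at 3.46 and 9.85 on the mock arrays and at 4.01 and 10.21 on those labelled infected. Mx1, an antiviral GTPase induced by interferon, was at 11.71 and 11.73 on the wild-type arrays numbered 2 and between 5.19 and 6.04 on the other 6. The first principal component held 59.9% of the variance and separated arrays numbered 1 from arrays numbered 2. Across genes, which are not independent replicates, arrays of the same genotype and number correlated at 0.991 to 0.996 and arrays of the same group at 0.970 to 0.985. The comparisons by label come first, with every array in its labelled group, and those by replicate number follow.

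**Figure D1:**
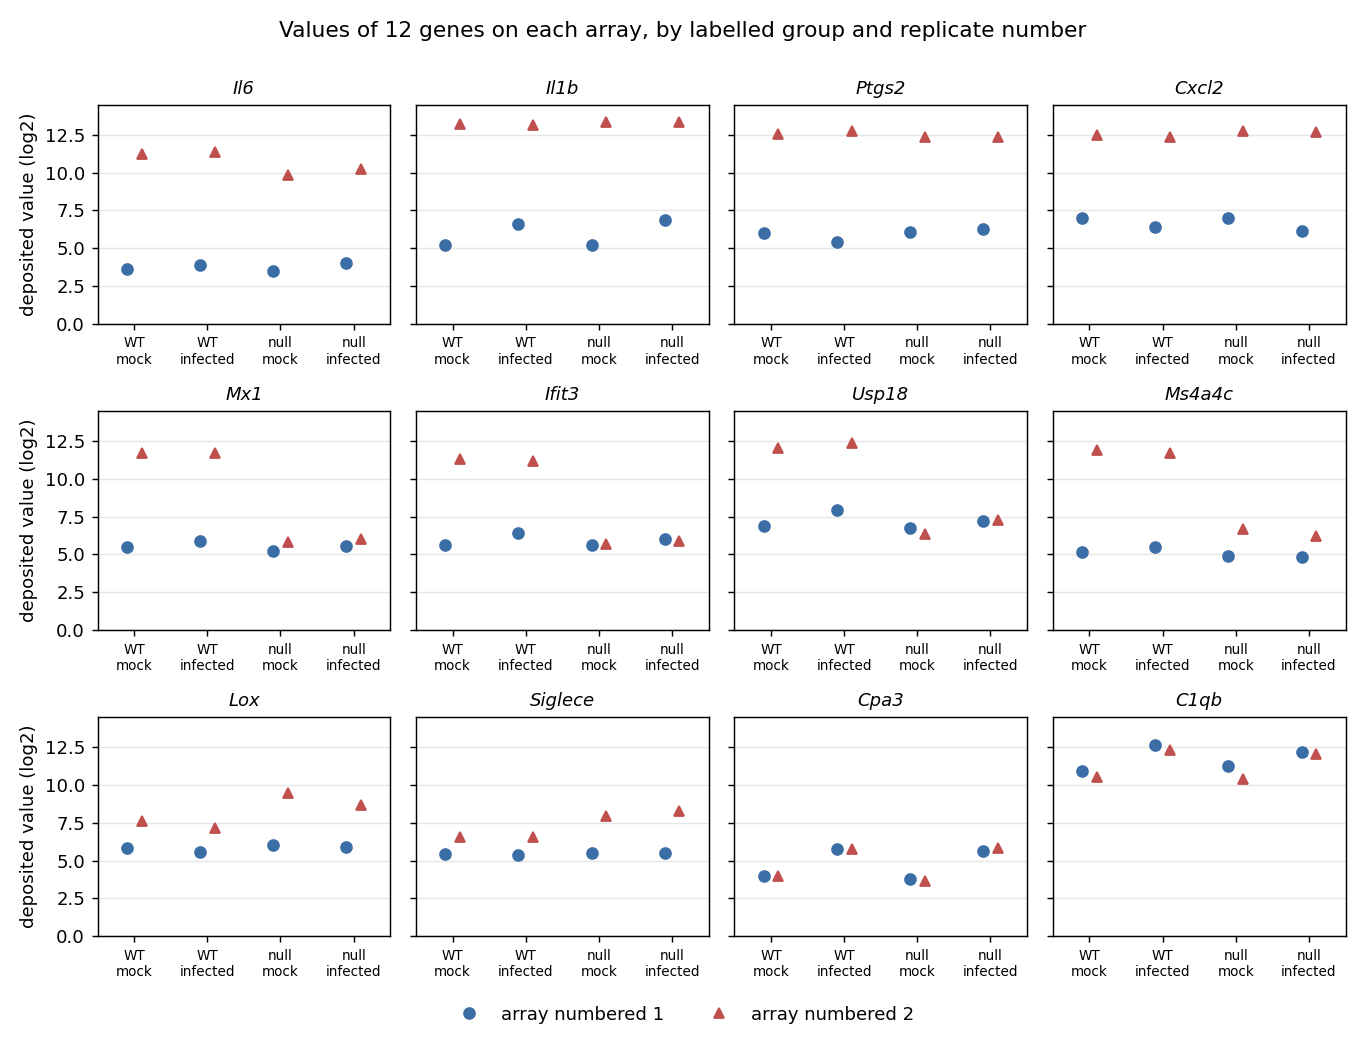
Deposited log2 values (vertical axis) of 12 genes on each of the 8 arrays, by labelled group (horizontal axis), with circles for arrays numbered 1 and triangles for arrays numbered 2. Il6 lies between 3.46 and 4.01 on the arrays numbered 1 and between 9.85 and 11.37 on those numbered 2, whatever the infection label, while Cpa3 follows the label.

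The first comparison asked which genes differed between wild-type macrophages labelled infected and mock. Cpa3, a carboxypeptidase of mast cell granules, was higher in the arrays labelled infected, from values at background on the mock arrays (log2 difference 1.79 ± 0.10, SE, n = 2 arrays per group, adjusted p = 0.0355). It was the 1 gene of 30142 past the threshold in limma, while 3158 genes had an unadjusted p under 0.05. No gene was lower at that threshold, and the smallest p values belonged to the small nucleolar RNA Snord118 (-1.56, adjusted p = 0.146), the spliceosomal RNA Rnu2-10 (-0.98, adjusted p = 0.309) and the microRNA Mir1952 (-0.64, adjusted p = 0.309). A second probe set of Snord118 gave -0.31. Single targets of bacterial sensing did not pass by label. None of the 28 measured inflammatory cytokines, 25 chemokines or 54 interferon-stimulated genes passed over all genes or when adjusted over the list alone, and the list medians were 0.05, -0.09 and 0.29. Il1b differed by 0.66 (adjusted p = 0.96), Il12b by 0.92 (adjusted p = 0.89) and Ccl2 by -0.88 (adjusted p = 0.90). Leaving out any 1 of the 8 arrays in turn ended the Cpa3 call (adjusted p = 0.157 to 0.418).

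With the replicate number as a block in the same fit, 232 genes were higher and 113 lower in the wild-type arrays labelled infected. The higher ones included the fatty acid desaturase Scd1 (1.85 ± 0.15, adjusted p = 0.00818), Cpa3 (adjusted p = 0.00818), the complement C1q subunits C1qb (1.75, adjusted p = 0.0143) and C1qc (1.61), the complement receptor Vsig4 (1.73), the metalloproteinase Mmp27 (1.68), the selenium carrier Selenop (1.53) and properdin, Cfp (1.49). The lower ones included Snord118 (adjusted p = 0.00818), the immunoglobulin segment Ighv11-1 (-1.20), the matrix proteoglycan decorin, Dcn (-1.10), Rnu2-10 (adjusted p = 0.0256), Snord14e (-0.90), the uroplakin Upk1b (-0.87), the pseudogene Morf4l1-ps1 (-0.87), Slc43a3 (-0.86) and Mir1952 (adjusted p = 0.0411). Adjusted over the list alone with the block, 1 of 25 chemokines was higher and 2 were lower. Of the cytokines only Ebi3, a shared interleukin subunit, passed with the block (0.90, adjusted p = 0.0227). Without the block the genes named before it, other than Cpa3, had adjusted p of 0.146 to 0.580. Of the 232 higher genes, 230 had a positive difference by label in the null macrophages, and of the 113 lower genes 110 had a negative one there, from other arrays. Over all genes, which are not independent replicates, the label effects in the 2 genotypes correlated at 0.518. Same-numbered arrays of the 2 genotypes may share a preparation, so the agreement is not an independent replication. Small nuclear and nucleolar RNAs made up 64 of the 113 lower genes.

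The fixed gene lists moved little by label in wild type. The inflammatory cytokine (camera adjusted p = 0.249), chemokine (adjusted p = 0.443), NF-kB feedback (adjusted p = 0.0692) and costimulation lists (adjusted p = 0.438) did not pass. Some others of infection responses passed with small medians: interferon-stimulated genes (camera adjusted p = 0.0289), type I interferon induction (0.09, adjusted p = 0.0297), interferon-gamma-type GTPases (0.34, adjusted p = 0.0476), antibacterial effectors (0.18, adjusted p = 0.00611) and inflammasome genes (0.23, adjusted p = 0.00536). With an estimated correlation the adjusted p were 0.913, 0.429, 0.851, 0.585 and 0.383. TCA cycle and respiratory chain (0.18, adjusted p = 4.39e-06), lysosomal (0.23, adjusted p = 1.62e-05), glycolysis (0.06, adjusted p = 0.0289) and housekeeping genes (0.05, adjusted p = 0.0289) passed too, with adjusted p of 0.429 to 0.477 with an estimated correlation. Macrophage identity and scavenger genes had a median of 0.17, with 3 of 32 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.00462, and adjusted p = 0.383 with an estimated correlation); C1qa, C1qb and C1qc led it. Resident large peritoneal macrophage genes had a median of 0.13, with 4 of 19 higher and 1 lower over the list alone (adjusted p = 0.00218, and adjusted p = 0.383 with an estimated correlation). Of 22 sterol synthesis and lipid efflux genes, 3 were higher over the list alone, and the median was 0.23 (adjusted p = 1.01e-05, and adjusted p = 0.383 with an estimated correlation); its leading members were Scd1, the receptor-degrading ligase Mylip (1.23), the lipid exporter Abcg1 (1.10) and the lipid transfer protein Pltp (1.09). MHC class II presentation genes had a median of 0.30, with 5 of 13 higher and 1 lower over the list alone (adjusted p = 0.000563, and adjusted p = 0.383 with an estimated correlation). Mesothelial, fibroblast and erythroid markers went the other way, with a median of -0.34 and 8 of 18 lower over the list alone (adjusted p = 1.01e-05, and adjusted p = 0.383 with an estimated correlation). With the block, 4 of these 18 markers passed over all genes and 10 over the list alone, among them Dcn, Upk1b, Sparc and Col1a2. Over all genes the block also called 4 sterol, 4 macrophage identity, 4 resident macrophage, 1 MHC class II and 1 inflammasome gene higher. Lower were 1 costimulation and 1 dendritic cell gene. Adjusted over the list alone it called, among others, 7 sterol, 7 respiratory chain, 7 lysosomal and 5 antibacterial genes higher. MHC class II genes were 8 higher and 1 lower, macrophage identity genes 7 and 3, and resident macrophage genes 7 and 1. The block also moved 3 list calls. The NF-kB feedback list passed with it (camera adjusted p = 0.00987, and adjusted p = 0.589 with an estimated correlation). The antioxidant and B lymphocyte lists passed without it (camera adjusted p = 0.0475 and 0.0454) but not with it (adjusted p = 0.0968 for each). Without the block, their adjusted p with an estimated correlation were 0.585 and 0.398. Fry without the block gave unadjusted p = 0.00278 for the B lymphocyte list and 0.0193 for resident macrophage genes. For mesothelial, fibroblast and erythroid markers it gave 0.0109. It gave 0.866 for interferon-stimulated genes and 0.773 for interferon-gamma-type GTPases.

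The same comparison was made in IFN-beta null macrophages. Cpa3 was again the 1 gene past the threshold, higher in the arrays labelled infected (log2 difference 2.03 ± 0.10, SE, n = 2, adjusted p = 0.0161), and 572 genes had an unadjusted p under 0.05 in limma. Its values were 3.76 and 3.65 on the mock arrays and 5.65 and 5.82 on those labelled infected, so the mock values were at background. No gene was lower at the threshold, and the smallest p values belonged to Slc43a3 (-0.96), Mir450-2 (-0.68) and the pheromone receptor Vmn2r96 (-0.90), each with an adjusted p of 1.0. No cytokine, chemokine or interferon-stimulated gene passed, and the list medians were 0.06, -0.14 and 0.28. C1qb differed by 1.26, C1qc by 1.16, Scd1 by 1.55 and the lymphoid chemokine Cxcl13 by 1.32, with adjusted p of 1.0. Leaving out any 1 array ended the Cpa3 call (adjusted p = 0.123 to 0.453).

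Among the lists in null macrophages, sterol synthesis and lipid efflux genes had a median of 0.30, with 2 of 22 higher when adjusted over the list alone (camera adjusted p = 1.14e-08, and adjusted p = 0.383 with an estimated correlation). Resident macrophage genes had a median of 0.20, with 2 of 19 higher over the list alone (adjusted p = 5.62e-06, and adjusted p = 0.337 with an estimated correlation). Cell cycle genes had a median of 0.16 and no member past the threshold (adjusted p = 2.38e-07, and adjusted p = 0.383 with an estimated correlation). Mast cell, basophil and eosinophil markers (0.08, adjusted p = 0.000102), lysosomal genes (0.16, adjusted p = 0.0195) and the unfolded protein response (-0.07, adjusted p = 0.0195) also passed, with adjusted p of 0.608 to 0.823 with an estimated correlation. The mesothelial, fibroblast and erythroid markers had a median of -0.06 (adjusted p = 0.177). With the block, 4 further lists passed: interferon-stimulated genes (adjusted p = 0.0185), antibacterial effectors (adjusted p = 0.0354), MHC class II (adjusted p = 0.0354) and macrophage identity genes (adjusted p = 0.00482). With an estimated correlation and the block, their adjusted p were 0.895, 0.581, 0.656 and 0.441. Fry without the block gave unadjusted p = 0.0122 for resident macrophage genes and 0.0178 for the mast cell, basophil and eosinophil list. It gave 0.853 for interferon-stimulated genes.

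Between genotypes in mock-labelled cells, interferon-stimulated genes were the group that stood lowest in the null, with a median of -1.19 over 54 members and all 54 negative. Mx1 differed by -3.12, Ifit3b by -3.07, Slfn4 by -3.05 and Ifit2 by -3.05. These differences lay within the spread of the wild-type mock pair, whose Mx1 values were 5.51 and 11.71, and these 4 had adjusted p of 0.634 to 0.650. No member passed over all genes or over the list alone. The list's camera adjusted p was 0.000608, and its adjusted p was 0.844 with an estimated correlation. No gene passed in limma, at 2257 genes with an unadjusted p under 0.05 and 4201 with the block. The smallest p values belonged to the epoxide hydrolase Ephx2 (0.78), Vmn2r96 (1.01) and Ms4a8a (0.73) on the higher side, and to Snord118 (-1.06), Rnu2-10 (-0.80) and the odorant receptor Olfr303 (-0.54) on the lower, each with an adjusted p of 0.632. TCA cycle and respiratory chain genes had a median of 0.23 (adjusted p = 5.70e-08, and adjusted p = 0.403 with an estimated correlation), and antioxidant genes one of 0.24 (adjusted p = 0.000117, and adjusted p = 0.403 with an estimated correlation). Among markers of other cells, B lymphocyte (-0.20, 1 of 16 lower adjusted over the list alone, adjusted p = 0.00218), T and NK lymphocyte (-0.19, adjusted p = 0.00228) and mast cell, basophil and eosinophil markers (-0.13, adjusted p = 0.0210) were lower, and resident macrophage genes were higher (0.12, 1 of 19 over the list alone, adjusted p = 0.00213). Adjusted p with an estimated correlation were 0.403, 0.716, 0.716 and 0.403. Sterol (0.27, adjusted p = 0.000342), unfolded protein response (0.24, adjusted p = 0.000154), housekeeping (0.22, adjusted p = 0.000154), glycolysis (0.13, adjusted p = 0.00968), prostaglandin (0.18, adjusted p = 0.0288) and antibacterial genes (0.17, adjusted p = 0.0210) passed too, with adjusted p of 0.403 to 0.728 with an estimated correlation. With the block, 4 more lists passed: interferon-gamma-type GTPases (median -0.71, adjusted p = 0.0085), NF-kB feedback genes (0.13, adjusted p = 0.0014), MHC class I (-0.32, adjusted p = 0.00239) and lysosomal genes (0.09, adjusted p = 0.0185). Their adjusted p with an estimated correlation and the block were 0.595, 0.524, 0.549 and 0.549.

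Between genotypes in cells labelled infected, the interferon-stimulated list was again lower in the null, with a median of -1.21 and 54 of 54 members negative. Ifit3b differed by -3.48, Ifit2 by -3.21, Mx1 by -3.01 and the interferon-limiting protease Usp18 by -2.92, each with an adjusted p of 1.0 (camera adjusted p = 5.99e-14 for the list, and adjusted p = 0.472 with an estimated correlation). Mesothelial, fibroblast and erythroid markers were higher in the null, with a median of 0.37 and 9 of 18 higher when adjusted over the list alone (adjusted p = 3.28e-15, and adjusted p = 0.214 with an estimated correlation). Cell cycle genes had a median of 0.18 (adjusted p = 6.49e-09, and adjusted p = 0.214 with an estimated correlation). Resident macrophage genes were higher (0.12, adjusted p = 8.57e-05) and B lymphocyte markers lower (-0.09, adjusted p = 0.00164), each with an adjusted p of 0.214 with an estimated correlation. Interferon-gamma-type GTPases (-1.04, adjusted p = 6.51e-05), MHC class I (-0.38, adjusted p = 4.34e-05) and MHC class II genes (-0.12, adjusted p = 9.98e-05) were lower. Sterol (0.26, adjusted p = 0.00164), unfolded protein response (0.11, adjusted p = 0.00519) and antioxidant genes (0.14, adjusted p = 0.0190) were higher. These 6 lists had adjusted p of 0.290 to 0.472 with an estimated correlation. No gene passed in limma, at 537 genes with an unadjusted p under 0.05 and 1318 with the block. The smallest p values belonged to Clca3a2 (1.49), the matrix proteins Sparc (1.16) and biglycan, Bgn (1.31), on the higher side, and to Htra1 (-0.49), Ms4a7 (-0.80) and Olfr94 (-0.48) on the lower, each with an adjusted p of 1.0. With the block, 5 more lists passed: inflammatory cytokines (adjusted p = 0.0496), inflammasome and cell death genes (adjusted p = 0.000283), costimulation (adjusted p = 0.00258), prostaglandin (adjusted p = 0.0178) and glycolysis genes (adjusted p = 0.0139). Their adjusted p with an estimated correlation and the block were 0.310, 0.271, 0.271, 0.279 and 0.572.

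The interaction asked whether the labelled infection effect differed between genotypes. The interferon-stimulated genes gave a median of -0.02 and no call (camera adjusted p = 0.224). Clca3a2 (1.31), Snord118 (1.34) and Olfr728 (0.55) had the smallest p values on the higher side, and Mir450-2 (-0.75), Vmn2r96 (-0.92) and the tetraspanin Tspan31 (-0.55) on the lower, each with an adjusted p of 0.988. No gene passed in limma, at 701 genes with an unadjusted p under 0.05 and 1463 with the block. Mesothelial, fibroblast and erythroid markers had a median of 0.28 (adjusted p = 0.000475, and adjusted p = 0.655 with an estimated correlation), and TCA cycle and respiratory chain genes one of -0.19 (adjusted p = 1.62e-05, and adjusted p = 0.680 with an estimated correlation). Cell cycle genes (0.22, adjusted p = 0.00738), T and NK lymphocyte (0.16, adjusted p = 0.0311) and mast cell, basophil and eosinophil markers (0.15, adjusted p = 0.0131) passed on the higher side. MHC class II (-0.19, adjusted p = 0.0131), housekeeping (-0.16, adjusted p = 0.00258), lysosomal (-0.13, adjusted p = 0.0190), inflammasome (-0.17, adjusted p = 0.0444) and antioxidant genes (-0.08, adjusted p = 0.0444) passed on the lower side. An estimated correlation gave these lists adjusted p of 0.655 to 0.680. With the block, 4 more lists passed: interferon-gamma-type GTPases (adjusted p = 0.0214), NF-kB feedback (adjusted p = 0.00105), unfolded protein response (adjusted p = 0.0214) and macrophage identity genes (adjusted p = 0.0259). Their adjusted p with an estimated correlation and the block were 0.624, 0.536, 0.624 and 0.536.

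The replicate number divided the arrays in both genotypes, so 5 comparisons by number were added after the values had been seen. Arrays were grouped by genotype and number, 2 arrays to each of the 4 cells, with the labelled infection as a term in the fit and no array moved to another label. The number is not a treatment, and each cell holds 1 array labelled mock and 1 labelled infected. If a number marks a preparation, each cell holds 1 preparation. The SE and p values by number would then measure the spread between arrays of a preparation and not between preparations.

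In wild-type macrophages, the arrays numbered 2 carried an acute inflammatory and interferon profile that the arrays numbered 1 lacked. Il6 was far higher, from background on the arrays numbered 1 (log2 difference 7.57 ± 0.12, SE, n = 2, adjusted p = 8.58e-10). The pyrogenic cytokine Il1b was 152-fold higher (7.25 ± 0.37), cyclooxygenase-2, Ptgs2, 123-fold (6.95 ± 0.17), and the early activation marker Cd69 rose from near background (6.59 ± 0.13). Ms4a4c (6.49), Trim30c (6.40), the interferon-induced RNA-binding protein Ifit1 (6.30) and the myeloid receptor Tarm1 (6.25) followed. Lower in the arrays numbered 2 were the chemokine receptor Cxcr4 (-2.63 ± 0.30, adjusted p = 0.000238), the potassium channel Kcnj2 (-2.58), the ubiquitin ligase subunit Fbxo32 (-2.44), the lipid-sensing nuclear receptor Pparg (-2.40), Cd300lb (-2.40), the prostaglandin D synthase Hpgds (-2.31), the inhibitory receptor Havcr2 (-2.30) and the secretase subunit Aph1c (-2.22). In all, 1901 genes were higher and 3095 lower, and of the 1062 that differed by a log2 value of at least 1, 651 were higher and 411 lower. The count was 2650 without the label term (1237 higher and 1413 lower), 3132 without wild-type mock array 1 (1277 and 1855), 3129 without wild-type mock array 2 (1399 and 1730) and 2437 without wild-type infected array 1 (1172 and 1265).

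Of the 54 interferon-stimulated genes, 53 were higher in the wild-type arrays numbered 2, both over all genes and over the list alone, with a median of 2.95; Cxcl10 (6.25), Mx1 (6.03) and Ifit3b (5.97) were among them. The list's camera adjusted p was 5.21e-68, and its adjusted p was 0.194 with an estimated correlation. Of 28 inflammatory cytokines 24 were higher (26 adjusted over the list alone, median 2.90), including the vasoactive peptide Edn1 (5.74) and Tnfsf15 (5.62). Of 25 chemokines 19 were higher (21 adjusted over the list alone, with 1 lower, median 2.82), including Cxcl2 (5.72), Ccl5 (5.63) and Cxcl9 (5.14). The cytokine and chemokine lists passed with the preset correlation (adjusted p = 7.65e-27 and 3.00e-21) and with an estimated one (adjusted p = 0.0240 for each). They were the only wild-type number calls of the 28 lists to hold with an estimated correlation. Of 21 costimulation genes 19 were higher, among them Cd40 (5.36), Vcam1 (4.61) and Icam1 (3.65), also adjusted over the list alone (adjusted p = 3.34e-21, and adjusted p = 0.0568 with an estimated correlation). Of 37 NF-kB and MAPK feedback genes 27 were higher and 1 lower (29 and 1 adjusted over the list alone), led by the inhibitor Nfkbiz (3.46), Traf1 (2.84) and Nfkbia (2.77) (adjusted p = 2.47e-19, and adjusted p = 0.195 with an estimated correlation). Interferon-gamma-type GTPases (18 of 22 higher and 1 lower, adjusted p = 2.41e-22), MHC class I (12 of 14 higher, adjusted p = 1.75e-12), antibacterial (18 of 30 higher and 2 lower, adjusted p = 1.92e-08), inflammasome (12 of 24 higher and 2 lower, adjusted p = 0.000584) and type I interferon induction genes (6 of 29 higher and 2 lower, adjusted p = 0.0222) were higher in number 2. TCA cycle and respiratory chain (6 of 24 lower, adjusted p = 9.73e-05) and housekeeping genes (2 of 14 lower, adjusted p = 0.0198) were lower. Their adjusted p with an estimated correlation were 0.194 to 0.653. Adjusted over the list alone the counts were 19 and 1, 12, 19 and 4, 12 and 6, 7 and 2, 8, and 4. Among other cell types' markers, 2 of 18 mesothelial, fibroblast and erythroid genes were higher, Pdgfrb (1.56) and Cdh5 (0.54), and that list did not pass (adjusted p = 0.0918). Neutrophil markers passed, with 4 of 21 higher and 1 lower (adjusted p = 0.0208, and adjusted p = 0.639 with an estimated correlation), as did dendritic cell markers, with 3 of 21 higher (adjusted p = 0.0381, and adjusted p = 0.310 with an estimated correlation).

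In IFN-beta null macrophages, the arrays numbered 2 showed the inflammatory part of that profile with less of the interferon part. Il1b was 157-fold higher (7.29 ± 0.37, SE, n = 2, adjusted p = 1.20e-06) and the itaconate-producing enzyme Acod1 84.5-fold (6.40 ± 0.22), and Il6 rose from background (6.29 ± 0.12). Ptgs2 (6.18), the neutrophil attractants Cxcl2 (6.15) and Cxcl3 (5.68), the protease inhibitor Serpinb2 (5.97) and Tarm1 (5.90) were also higher. Lower were the exchange factor Rasgrp3 (-3.08 ± 0.24), the signalling regulator Rgs2 (-2.99), Havcr2 (-2.80), the deiodinase Dio2 (-2.77), Cxcr4 (-2.54), Hpgds (-2.47), Fbxo32 (-2.34) and the xylosyltransferase Xylt1 (-2.31). In all, 1239 genes were higher and 1083 lower, a balance that depended on the setting. It was 473 and 241 among the 714 that differed by at least 1, and 715 and 302 of 1017 without the label term. It was 1099 and 518 without null mock array 1, 800 and 800 without null infected array 1, and 755 and 490 of 1245 without null infected array 2. Hpgds (adjusted p = 0.102) and Fbxo32 (adjusted p = 0.103) were lost without the label term.

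Of 28 cytokines 21 were higher in the null arrays numbered 2 (23 adjusted over the list alone), with Inhba (4.33) and Tnf (4.32) after Il1b and Il6. Of 25 chemokines 16 were higher (17 adjusted over the list alone), including Ccl5 (5.35) and Cxcl1 (4.69), and of 21 costimulation genes 15 (19 adjusted over the list alone), including Cd40 (4.46) and Icosl (3.44). These 3 lists passed with the preset and with an estimated correlation (adjusted p = 0.0145, 0.0145 and 0.0345 with the latter). Of 37 NF-kB feedback genes 27 were higher (28, with 3 lower, adjusted over the list alone; adjusted p = 4.72e-32, and adjusted p = 0.120 with an estimated correlation). Of the 54 interferon-stimulated genes, 29 were higher and 1 lower (35 and 1 adjusted over the list alone), with a median of 0.56 and Ifit1 (3.15), the nucleic acid sensor Zbp1 (2.65), Ifih1 (2.64) and Isg15 (2.53) in front (adjusted p = 1.34e-22, and adjusted p = 0.352 with an estimated correlation). Antibacterial (18 of 30 higher and 1 lower, adjusted p = 2.33e-19), interferon-gamma-type (15 of 22 higher and 2 lower, adjusted p = 2.11e-15), MHC class I (8 of 14 higher, adjusted p = 5.11e-11), sterol (10 of 22 higher and 2 lower, adjusted p = 6.58e-05), inflammasome (9 of 24 higher and 4 lower, adjusted p = 0.000541), antioxidant (6 of 23 higher and 1 lower, adjusted p = 0.00497) and MHC class II genes (3 of 13 higher, adjusted p = 0.0356) were higher. Lysosomal genes were lower (8 of 27 lower and 2 higher, adjusted p = 7.07e-05). With an estimated correlation the adjusted p were 0.0718 to 0.664. Adjusted over the list alone the counts were 19 and 2, 15 and 2, 10, 13 and 4, 10 and 4, 6 and 2, 3 and 1, and 12 and 2. Between the genotypes, 855 genes were higher in the arrays numbered 2 in both (78.1 if independent), 931 were lower in both (111 if independent) and 17 went opposite ways. The 2 comparisons shared each gene's spread estimate and the label term. The counts under independence are therefore not a chance level for these calls. The number effects correlated at 0.732 across genes, which are not independent replicates.

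**Figure D2:**
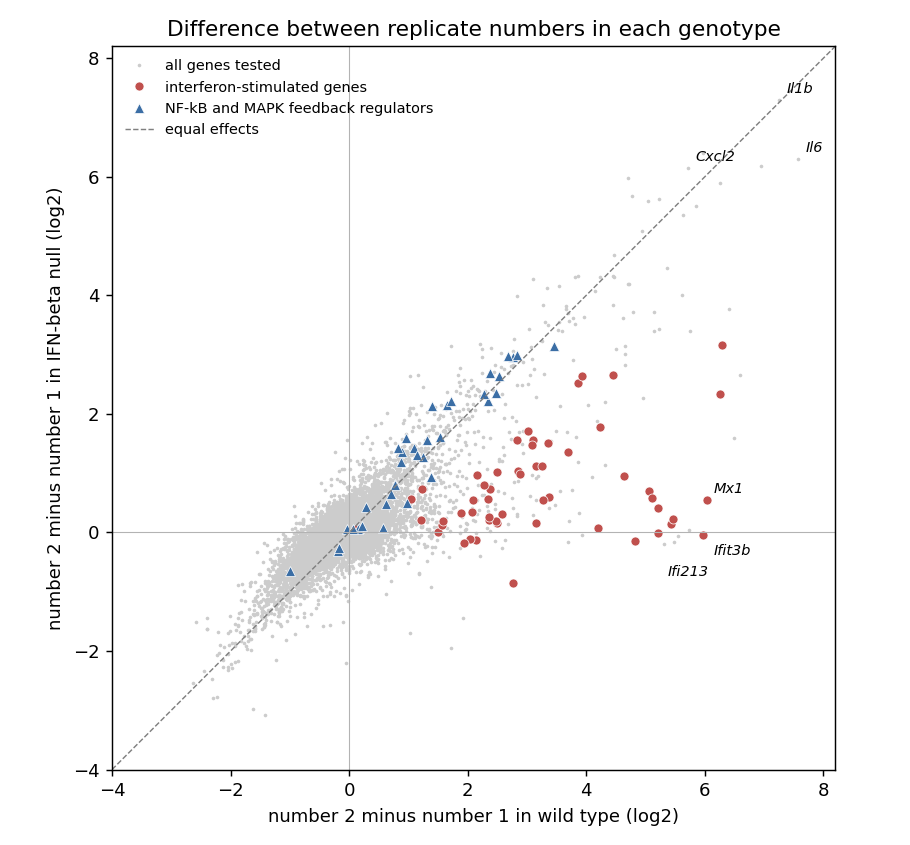
Log2 difference between arrays numbered 2 and 1 in wild-type (horizontal axis) and IFN-beta null macrophages (vertical axis), 1 point per gene, with interferon-stimulated genes as red circles, NF-kB and MAPK feedback genes as blue triangles and the dashed line at equal effects. The feedback genes lie near the line and most interferon-stimulated genes below it, as with Mx1 at 6.03 in wild type and 0.55 in the null.

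Genotypes were then compared within each number. Among arrays numbered 1, interferon-stimulated genes had a median of -0.19 in the null relative to wild type, with no member past the threshold over all genes and 3 lower when adjusted over the list alone (camera adjusted p = 1.32e-12, and adjusted p = 0.741 with an estimated correlation). Mesothelial, fibroblast and erythroid markers had a median of 0.26, with 6 of 18 higher over the list alone (adjusted p = 1.63e-11, and adjusted p = 0.350 with an estimated correlation), and resident macrophage genes one of 0.23, with 3 of 19 higher (adjusted p = 7.07e-09, and adjusted p = 0.350 with an estimated correlation). B lymphocyte markers had a median of -0.13 (adjusted p = 0.000171, and adjusted p = 0.350 with an estimated correlation). MHC class II (-0.10, adjusted p = 0.000303), MHC class I (-0.13, adjusted p = 0.00200) and interferon-gamma-type genes (-0.11, adjusted p = 0.0310) were lower. Unfolded protein response (0.12, adjusted p = 0.000595), prostaglandin (0.12, adjusted p = 0.00919), cell cycle (0.07, adjusted p = 0.00919), chemokine (0.04, adjusted p = 0.0310) and glycolysis genes (0.06, adjusted p = 0.0480) were higher. Adjusted p with an estimated correlation were 0.350 to 0.865. Dcn differed by 1.13 (adjusted p = 0.28). The 1 gene past the threshold was the predicted gene Gm5945 (-1.10 ± 0.11, adjusted p = 0.0434), named after its value was seen because its provisional symbol falls outside the naming rule. In limma 1480 genes had an unadjusted p under 0.05. The synaptic adhesion protein Clstn1 (0.91, adjusted p = 0.0796), Itm2a (0.64) and Itgb3bp (0.70) were nearest on the higher side, and Rab6b (-1.12, adjusted p = 0.121), the transferrin receptor Tfrc (-0.89) and Trav6d-7 (-0.72) on the lower. The count became 0 with quantile normalization, with dim genes left out, without the label term, and without wild-type infected array 1, null mock array 1 or null infected array 1. It was 5 without wild-type mock array 1, 6 without wild-type array 2 of either label and 7 without null array 2 of either label. Clstn1 passed in those last 4 fits (adjusted p = 0.0254 and 0.0356), Rab6b in all 5 (adjusted p = 0.0168 to 0.0290) and Tfrc without wild-type array 2 of either label (adjusted p = 0.0254).

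Among arrays numbered 2, interferon-dependent antiviral genes were far lower in the IFN-beta null macrophages. Ifit3b was 77.8-fold lower (-6.28 ± 0.16, SE, n = 2, adjusted p = 1.08e-08), the DNA-binding protein Ifi213 65.6-fold (-6.04) and Mx1 56.0-fold (-5.81 ± 0.11, adjusted p = 4.12e-09). Ifi208 (-5.79), Ifit2 (-5.77), Ifit3 (-5.45), Usp18 (-5.41) and Ms4a4c (-5.37) were close behind. Higher in the null were the collagen crosslinker Lox (1.68 ± 0.15, 3.21-fold), Tgfbi (1.63), the replication fork protein Radx (1.61), the inhibitory lectin Siglece (1.56), the oxysterol hydroxylase Cyp7b1 (1.49), the interleukin-1 receptor Il1r1 (1.46), the chemokine Ccl17 (1.46) and the telomere protein Pot1b (1.40). In all, 998 genes were higher and 778 lower. The balance depended on the setting: 67 were higher and 285 lower among the 352 that differed by at least 1, 661 and 686 with quantile normalization, 1485 and 761 with dim genes left out, and 208 and 399 without the label term. It was 233 and 565 without wild-type mock array 2, 321 and 498 without null mock array 2, and 265 and 426 without null infected array 2, which are totals of 607 without the label term and then 798, 819 and 691. Without the label term Tgfbi, Radx, Cyp7b1, Il1r1 and Ccl17 were lost (adjusted p = 0.0673 to 0.216). Tgfbi and Radx were also lost without wild-type mock array 2 (adjusted p = 0.106 and 0.104) or null infected array 2 (adjusted p = 0.0605 and 0.0626), and Tgfbi with quantile normalization (adjusted p = 0.0677).

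Of 54 interferon-stimulated genes, 51 were lower in the null arrays numbered 2 (53 adjusted over the list alone), with a median of -2.28 (camera adjusted p = 7.92e-81, and adjusted p = 0.298 with an estimated correlation). Of 22 interferon-gamma-type GTPases and regulators 15 were lower (19 lower and 1 higher adjusted over the list alone), led by the Fc receptor Fcgr1 (-4.07), Gbp9 (-3.44), Gvin1 (-3.05) and Igtp (-2.80) (adjusted p = 1.19e-19, and adjusted p = 0.317 with an estimated correlation). Of 14 MHC class I presentation genes 8 were lower (12 adjusted over the list alone), including the peptide transporter Tap1 (-1.49) and the immunoproteasome subunits Psmb9 (-1.06), Psmb10 (-0.98) and Psmb8 (-0.89) (adjusted p = 5.13e-11, and adjusted p = 0.380 with an estimated correlation). Of 28 cytokines 9 were lower and 1 higher (11 and 2 adjusted over the list alone), among them the death ligand Tnfsf10 (-4.12), Il15 (-2.87) and Il27 (-2.21) (adjusted p = 0.00460, and adjusted p = 0.298 with an estimated correlation). Of 21 costimulation genes 7 were lower and 1 higher (8 and 1 adjusted over the list alone), including Cd69 (-3.90), Il15ra (-2.15) and Cd86 (-2.11) (adjusted p = 0.0109, and adjusted p = 0.484 with an estimated correlation). Among 30 antibacterial genes 3 were lower, the nitric oxide synthase Nos2 (-2.05), complement factor Cfb (-1.56) and the peptidoglycan sensor Nod1 (-1.53), and 4 were higher, including Clec4n (1.13), with 3 and 7 adjusted over the list alone (adjusted p = 0.106). Of 37 NF-kB feedback genes, Irak3 (0.75) was higher and Zfp36 (-0.60) lower, with 7 higher and 2 lower adjusted over the list alone and a median of 0.08 (adjusted p = 0.0338, and adjusted p = 0.559 with an estimated correlation). Of the chemokines, Cxcl10 (-3.72), Ccl12 (-3.70) and Cxcl9 (-1.41) were among 6 lower and Ccl17 among 2 higher (7 and 6 adjusted over the list alone, adjusted p = 0.631). Mesothelial, fibroblast and erythroid markers were higher beside these groups, with Dcn (1.20), Sparc (0.82), Pdgfrb (0.71) and Col1a2 (0.61) past the threshold, 5 of 18 adjusted over the list alone (adjusted p = 0.0423, and adjusted p = 0.559 with an estimated correlation). T and NK lymphocyte markers were lower, with a median of -0.16, 0 of 22 positive, 2 past the threshold and 3 adjusted over the list alone (adjusted p = 0.00279, and adjusted p = 0.528 with an estimated correlation). B lymphocyte markers had a median of -0.14 and no member past the threshold (adjusted p = 0.0338, and adjusted p = 0.528 with an estimated correlation), and resident macrophage genes one of 0.20, with 2 of 19 higher, and 3 higher and 1 lower adjusted over the list alone (adjusted p = 0.0201, and adjusted p = 0.528 with an estimated correlation). Of the metabolic and stress lists, respiratory chain (2 of 24 higher, adjusted p = 1.22e-06), unfolded protein response (2 of 23, adjusted p = 7.71e-05), housekeeping (1 of 14, adjusted p = 0.00291), glycolysis (1 of 22 higher and 1 lower, adjusted p = 0.00362), prostaglandin (3 of 16, adjusted p = 0.00391) and cell cycle genes (4 of 29 higher and 2 lower, adjusted p = 0.00678) were higher. Inflammasome genes were lower (5 of 24 lower and 1 higher, adjusted p = 0.0143). An estimated correlation gave these lists adjusted p of 0.298 to 0.538. Adjusted over the list alone the counts were 5, 4, 1, 11 and 2, 4, 6 and 2, and 9 and 3.

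The last comparison asked whether the difference between numbers itself differed between genotypes. It was smaller in the null for Ifit3b (-6.02 ± 0.22, SE, n = 2 per cell, adjusted p = 4.89e-07), Ifi208 (-5.64), Ifi213 (-5.62), Ifit1bl1 (-5.51) and Mx1 (-5.48). It was larger in the null for Pot1b (1.60 ± 0.15), Siglece (1.49), Lox (1.42), Tmem154 (1.38) and haptoglobin, Hp (1.38). Of 54 interferon-stimulated genes 50 passed on the lower side (53 adjusted over the list alone), with a median of -2.11 (camera adjusted p = 1.23e-95, and adjusted p = 0.232 with an estimated correlation). No NF-kB feedback gene passed over all genes or over the list alone (median 0.08, adjusted p = 0.119). On the lower side were also interferon-gamma-type (13 of 22, adjusted p = 4.93e-21), MHC class I (3 of 14, adjusted p = 1.89e-08), cytokine (7 of 28, with 1 higher, adjusted p = 0.000814), costimulation (4 of 21, adjusted p = 0.0126), inflammasome (4 of 24, adjusted p = 0.0195) and T and NK lymphocyte genes (1 of 22, adjusted p = 0.00759). On the higher side were sterol (2 of 22, adjusted p = 1.35e-07) and antioxidant genes (2 of 23, adjusted p = 2.36e-05), and with no single gene respiratory chain (median 0.22, adjusted p = 0.000244), housekeeping (0.24, adjusted p = 0.0272) and lysosomal genes (0.13, adjusted p = 0.0285). Their adjusted p with an estimated correlation were 0.232 to 0.671. Adjusted over the list alone, the counts on the lower and then the higher side were 16 and 1, 7 and 0, 9 and 1, 4 and 1, 4 and 1, and 1 and 0. For the sterol and antioxidant genes they were 12 and 8 higher, with 1 lower in each. In all, 89 genes passed on the higher side and 341 on the lower. The higher side moved more with the setting: it was 33 against 252 among the 285 with a difference of at least 1, 11 against 168 of 179 without the label term, and 44 against 345 with quantile normalization. It was 55 against 239 without wild-type mock array 1, 34 against 287 without wild-type infected array 1, 34 against 281 without null infected array 1, and 143 against 317 without wild-type infected array 2. Lox, Tmem154 and Hp were lost with quantile normalization (adjusted p = 0.0732, 0.0881 and 0.114) and without the label term (adjusted p = 0.282, 0.196 and 0.115). Tmem154 was also lost without wild-type infected array 1, null mock array 1 or null infected array 1 (adjusted p = 0.0542 to 0.0971). Hp was lost without wild-type mock array 1, wild-type infected array 2, null mock array 1 or null infected array 1 (adjusted p = 0.0605 to 0.132).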

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

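The comparisons by replicate number, the test of exchanged labels, the test of a preparation difference and the count of other splits were chosen only after the result was seen.

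The difference between replicate numbers itself differed between genotypes for 430 genes, by limma's interaction test. It was larger in the null for Pot1b (1.60), Siglece (1.49), Lox (1.42), Tmem154 (1.38) and Hp (1.38), and smaller for Ifit3b (-6.02), Ifi208 (-5.64), Ifi213 (-5.62), Ifit1bl1 (-5.51) and Mx1 (-5.48). Tmem154 was lost without wild-type infected array 1, null mock array 1 or null infected array 1, and Hp without wild-type mock array 1, wild-type infected array 2, null mock array 1 or null infected array 1 (adjusted p = 0.0542 to 0.132). Outside the named genes, 2664 of 41898 probe sets with no single gene symbol differed between numbers in wild type, 923 higher and 1741 lower, a signal in data that the comparisons above did not use.

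The inflammatory genes differed by replicate number and not by infection label. Of 90 members of the cytokine, chemokine and NF-kB lists together, 77.8% were higher in number 2 in wild type and 71.1% in the null, against at most 1.11% higher in the arrays labelled infected with the number in the fit. Among 35 splits of the 8 arrays into 4 and 4, the split by number was the 1 that called as many genes (2649 genes, highest other 2). It was picked after it was seen among 3 that the labels define, and with that choice counted the splits are too few for a share under 0.05. Each split was also fitted alone, so in the others the difference between numbers stayed in the spread. Few calls there therefore decide nothing. A candidate explanation is that the arrays labelled mock 2 and infected 1 were exchanged in both genotypes, which the 71.1% allows. A difference between preparations with the labels right, in which the mock cells numbered 2 met a stimulus and the infection had little effect, would leave the same 71.1% and 1.11%, so the 2 cannot be told apart here, and every array is reported under its own label.

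Among arrays numbered 2, interferon-stimulated genes were lower in the IFN-beta null than in wild type. A response of the null arrays that was weaker to the same degree for all genes would lower the NF-kB feedback genes as well. The slope of the null's number effect on the wild type's was 1.06 over that list (95% bootstrap interval over 37 members 0.998 to 1.12). It was 0.224 over the interferon-stimulated list (0.155 to 0.302). The intervals cover list members on the same arrays and not variation between arrays. Fewer genes differed between numbers in the null (2322 against 4996 in wild type), so a response weaker for other genes too is not excluded. The deposited arrays were too alike in level (medians 5.31 to 5.50) for differences in level to account for the lower list. Quantile normalization gave a list median of -2.31 against -2.28 as deposited. Since it could move values only a little, it does not test the normalization used by the submitters. The loss of IFN-beta may account for the lower interferon-stimulated genes, as a hypothesis found on the same arrays and not itself tested here. It rests on the genotype labels, which Ifnb1 could not check, and not on the infection labels. Ifnb1, low on every array, was 0.29 higher in number 2 than in number 1 in wild type (limma adjusted p = 0.0768). Among arrays numbered 2 its null minus wild-type difference was 0.16 (limma adjusted p = 0.348).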

How the results depend on the processing

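The alternatives for the comparisons by number were chosen only after the result was seen. Among single genes, the alternatives for the comparisons by label left 385 values with their direction and side of the threshold, 18 lost the threshold, 3 gained it and 4 moved, all 4 the Ifnb1 interaction; for the added comparisons these were 792, 26, 11 and 0. No called gene changed sign. Genes changed by label numbered 1 in each genotype. They numbered 0 with the dim genes left out (fewer genes tested), 0 with only the 4 arrays compared and 0 without any 1 array (lowest and highest 0). The dim filter left out Cpa3 itself, so it was no test of that call. With the replicate block 345 genes were called in wild type. By gene over all genes and by camera, the block changed no call beyond these 345 genes and the calls given with the comparisons. Adjusted over the list alone it called more members, among them 2 chemokines higher and 2 lower for infection in the null, 8 cell cycle genes higher in infected null cells, and 5 mesothelial, fibroblast and erythroid markers higher and 99 small nuclear and nucleolar RNAs lower in mock null cells, from 0 each. The genotype and interaction counts by label were 0 under every alternative. None of these alternatives fitted the difference between numbers separately in each genotype. Where that difference varied with genotype, as for the interferon-stimulated genes, it stayed in the spread. The counts of 0 therefore do not show that the genotypes were alike. Between numbers in wild type, 4996 genes became 2650 without the label term, 1062 with a minimum log2 difference of 1 and 2437 to 5356 without 1 array. In the null, 2322 became 1017, 714 and 1245 to 2689. Genotype in number 1, 1 gene, became 0 with quantile normalization, 0 with dim genes left out, 0 without the label term and 0 to 7 without 1 array. Genotype in number 2, 1776 genes, became 607 without the label term, 352 with the minimum and 691 to 2305 without 1 array. The interaction by number, 430 genes, became 179, 285 and 294 to 460. Lists passing fell with an estimated correlation from 16 to 0 for infection in wild type, 6 to 0 in the null, 13 to 0 and 11 to 0 for genotype in mock and infected cells, 10 to 0 for the interaction, 16 to 2 and 13 to 3 between numbers in wild type and null, 12 to 0 and 19 to 0 for genotype in numbers 1 and 2, and 12 to 0 for the interaction by number. Quantile normalization and the dim filter gave 6 and 6 for infection in wild type and 4 and 6 for the interaction, and the block gave 10 for infection in the null. Hpgds in wild type was lost without the label term (adjusted p = 0.0682). Beyond these constructions the cause was not tested. A group left with 1 array was assumed to vary like the others, and leaving out mock 2 and infected 1 in both genotypes would leave 1 array per group, with no test in the fit by group or of the interaction; an additive fit to those 4 arrays was not run. The pseudocount was not run, since the values are log2. Ifnb1 lay near the background signal (medians 3.85 to 4.06), where a change is hard to see.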

Other observations

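The comparisons by replicate number, the list of small nuclear and nucleolar RNAs and the count of mast cell list members near background were chosen only after the result was seen. The sterol synthesis and lipid efflux list differed between genotypes in the arrays numbered 2 at the preset correlation. Of 22 sterol synthesis and lipid efflux genes, 12 were higher and 1 lower in the null (14 and 1 adjusted over the list alone), including the mevalonate pathway enzymes Mvd (1.17), Sqle (1.06) and Lss (0.87), while the interferon-induced oxysterol enzyme Ch25h was lower (-1.62). The list's camera adjusted p was 1.67e-08, and its adjusted p was 0.298 with an estimated correlation. Of 23 antioxidant genes 8 were higher and 1 lower (11 and 1 adjusted over the list alone), among them the cystine transporter Slc7a11 (1.13), Gclc (0.87), Abcc1 (0.75) and Hmox1 (0.73) (adjusted p = 8.61e-08, and adjusted p = 0.484 with an estimated correlation). Among 32 macrophage identity genes, the efferocytosis receptor Mertk (-1.46), Tlr9 (-1.37) and Maf (-1.25) were among 5 lower and Irf4 (1.34) among 4 higher (7 and 8 adjusted over the list alone, adjusted p = 0.972).

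Lysosomal and autophagy genes were lower in the wild-type arrays numbered 2, 13 of 27 over all genes and 16 adjusted over the list alone, with Gabarapl1 (-1.22), Atg7 (-1.13) and the cholesterol transporter Npc1 (-1.06) in front (camera adjusted p = 2.34e-06, and adjusted p = 0.310 with an estimated correlation). Of 23 unfolded protein and stress response genes 9 were lower (10 adjusted over the list alone), led by Ddit3 (-1.17) and Atf6 (-0.93) (adjusted p = 0.0152, and adjusted p = 0.653 with an estimated correlation). The histamine-forming enzyme Hdc was higher in the arrays numbered 2, by 3.45 in wild type and 3.10 in the null. By label, 18 of 1869 small nuclear and nucleolar RNAs were lower in the wild-type arrays labelled infected when adjusted over the list alone (median -0.27), and with the block 565 were lower and 10 higher over the list alone, or 64 and 1 over all genes. In the null the median was -0.11, and 0 passed in limma with or without the block, over all genes or the list alone (572 and, with the block, 1552 of all genes had an unadjusted p under 0.05). As a set these RNAs were lower by label in both genotypes, with 247 of 1869 positive in wild type and 484 in the null. Without the block, camera with an estimated correlation gave unadjusted p = 0.00256 in wild type and 0.00475 in the null. Fry gave unadjusted p = 0.000245 and 0.0113.

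Genes higher in the arrays labelled infected with the number in the fit included Cpa3, at 1.79 in wild type and 2.03 in the null. Mast cells would bring their other abundant transcripts, and the median over the 18 other mast cell, basophil and eosinophil markers was 0.0795 in the null (95% bootstrap interval 0.0110 to 0.173) and -0.111 in wild type (-0.204 to 0.000665). The whole list of 19, Cpa3 included, passed in the null (adjusted p = 0.000102, and adjusted p = 0.608 with an estimated correlation), where the tryptase Tpsb2 and the chymase Cma1 were 0.37 and 0.33 higher (adjusted p = 1.0). Since 9 of the 18 lay within 1 of the highest background median and the list mixes cell types, mast cell content stays open. The resident list was higher with the number in the fit (larger camera p of the genotypes 0.000302, medians 0.127 and 0.204). Its camera adjusted p was 0.455 and 0.441 with an estimated correlation. Vsig4 is a member of that list, so the list is no separate evidence for Vsig4. The medians were also small beside its difference of 1.73 in wild type. More resident macrophages in the arrays labelled infected may contribute to C1qb and its like, which the list does not settle. Infection itself stays open beside more resident macrophages, and if labels had been exchanged the differences by label would be differences between preparations.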
